A study of Homo sapiens with 24 samples.

How the data were processed

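RNA sequencing of 24 libraries was analysed, 6 each of parental KYSE450 cells, chemoresistant cells titled KYSE450DDP, and the drug tolerant persister (DTP) cells of both. Groups and replicate numbers were taken from the sample labels. Per the labels' protocols, cells grew in RPMI-1640 with 10% fetal bovine serum, RNA was extracted with TRIzol and libraries followed standard Illumina protocols. The submitters' processing notes name the genome build GRCh38. The aligner, the counting tool, the annotation release and the strandedness of the libraries are not given in the sources used here.

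The authors deposited FPKM values (fragments or reads per kilobase of gene, scaled to assigned reads), per the file headers, in 1 table of 61251 genes with a column per library. Of these genes, 20150 were listed at 0 in every library and 646 were unannotated loci. Gene IDs were looked up in GENCODE release 29, which held 58337 of them (95.24%) and gave coordinates and biotypes. Within each library the FPKM values were whole multiples of the value of 1 read, so reads were recovered from them. All 41101 genes with a value above 0 came out as whole reads, within 0.02 reads or a relative 5e-08. Of 14903 genes with at least 50 reads, 99.98% also had a whole implied gene length. Recovered totals ran from 14947379 to 37989445 reads per library. A count of 0 allows up to 3 reads, or 0.079 to 0.201 CPM, which covers counting error only. The recovered reads served to state depth and for an alternative test, while the main test used the deposited FPKM.

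A count model had been planned before the data were examined, with a stated replacement for a table of normalized values. As the values are FPKM, that replacement was used: limma 3.58.1 with a mean-variance trend in R 4.3.3, on log2(FPKM + 1), with the 4 group means fitted to all 24 libraries. Fold changes are on this scale, which understates the change of genes at low levels. Genes with a mean of at least 1 FPKM in at least 1 group were tested, 13729 in all. Tests were two-sided and p-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. A further count took genes with an absolute log2 fold change of at least 1. The comparisons were parental DTP against parental, chemoresistant DTP against chemoresistant, chemoresistant against parental, chemoresistant DTP against parental DTP, and the difference of the DTP change between the lines.

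The gene lists, the alternatives and the rule for named genes were fixed before the data were examined, except where a test is said to have been chosen later. Genes were named in 3 ways. The first were GDF15, GFRAL, NFE2L2, KEAP1, GCLC, GCLM, FDX1 and SLC31A1. The next were the 5 largest rises and 5 largest falls among protein coding genes past the threshold with a mean of at least 5 FPKM in the higher group and, except for the difference of DTP changes, no overlap of single libraries. The last were up to 4 members with the largest changes per list described, with a mean of at least 1 FPKM in the higher group. Of these, 1 gene is not reported here. The rule had been written in CPM, and FPKM took their place as it provided.

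There were 34 lists with 878 members, of which 877 matched a gene. They covered glutathione synthesis and use, NRF2 targets, cuproptosis, copper transport, metallothioneins, ferroptosis, ATF4 targets, endoplasmic reticulum chaperones, heat shock, p53 targets, mitosis, DNA replication, nucleotide excision and crosslink repair, drug transporters, persister-associated genes, mesenchymal, epithelial junction, basal squamous and squamous differentiation genes, hypoxia and glycolysis, interferon-stimulated genes, NF-kB cytokines, lipid synthesis, the tricarboxylic acid cycle, the nuclear-encoded respiratory chain, mitochondrial mRNAs, and lysosome and autophagy genes. Control lists held markers of fibroblasts, leukocytes, endothelium, glandular epithelium and erythroid cells, nuclear-retained RNAs and replication-dependent histones. Lists with at least 3 tested members (30) were tested with camera, which compares a list with the other genes, at a preset inter-gene correlation of 0.01. P-values were adjusted over the 150 pairs of list and comparison. Of these, 46 passed, and 23 passed with an estimated correlation. Some lists share members, so their tests are not independent. CHAC1 and SLC7A11 are in the glutathione and ATF4 lists, and GCLC, GCLM, GSR and SLC7A11 in the glutathione and NRF2 lists. Members of some lists share reads with near-identical copies (HSPA1A and HSPA1B, the metallothioneins MT1F and MT1X, AKR1C1, AKR1C2 and AKR1C3, the keratin 6 and SPRR2 genes, and histones), so the split of reads between such copies is uncertain, as it is between overlapping genes on opposite strands.

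The alternatives were relative log expression and upper-quartile factors, no filter, a stricter filter (1 CPM in 6 libraries and a mean of 50 reads), only the 12 libraries of the groups compared, the replicate number as a block, voom on the recovered reads, protein coding genes only, a pseudocount of 0.1, fry in place of camera, and each library left out in turn. The overlap of comparisons with the same controls was set against 50 simulations of unchanged groups. For the closing section, 100 splits of the libraries were drawn per comparison, and trends with GC content and gene length were removed with splines of 5 degrees of freedom. Simulated reads for parental DTP against parental (11609 genes tested) were used to test the fits: 64 of 67 genes changed 1.5-fold, 64 of 67 changed 2-fold and 66 of 66 changed 4-fold were called, with 6 calls among unchanged genes (3% of calls). In a separate simulation (11615 genes, 29 lists) 1 of 1 shifted list was found with 0 calls among lists sharing no member with it, and in another (9462 genes, 183 windows) 1 of 1 shifted chromosome window with 0 others. Reads of each gene were drawn independently and with a common spread, so these simulations do not measure errors that arise from correlated genes. In the first simulation the changed genes were few and went up or down at random, and no trend of libraries with GC content was drawn. Its 3% of calls therefore does not carry over to the comparisons reported here. Tables were read with Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.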

Results

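Messenger RNA levels were measured by RNA sequencing in 24 libraries of KYSE450, an established line of human oesophageal squamous cell carcinoma. The libraries fell into 4 groups of 6: the parental line, a chemoresistant one titled KYSE450DDP, and the drug tolerant persister (DTP) state of each line. Persister cells are the fraction of a tumour cell population that survives a drug without a resistance mutation. The labels name neither the drug nor its dose, do not explain the suffix DDP, and they list no treatment of the sequenced cultures. Nor do they say whether the 6 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Deviations of single libraries from their group means followed the GC content of genes, with Spearman rho from -0.64 to 0.655 by library. The main fit did not correct for this trend. Library totals recovered from the deposited values ran from 14947379 to 37989445 reads. At these depths a count of 0 allowed up to 0.079 to 0.201 CPM. Of 61251 genes in the table, 13729 reached a mean of 1 FPKM in at least 1 group and were tested.

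The series title concerns GDF15, its receptor GFRAL, the transcription factor NRF2, the glutathione synthesis enzyme GCLC and cuproptosis, a form of cell death set off by copper. GDF15, a secreted cytokine of stressed cells, was at 0.607 ± 0.123 FPKM in parental cells and at 20.1 ± 2.70 in parental DTP cells (SD, n = 6 each). In the chemoresistant line it was at 24.8 ± 1.75 FPKM, and at 77.3 ± 11.04 in that line's DTP cells. GDF15 (ENSG00000130513) lies on chromosome 19 from 18374731 to 18389176 of GRCh38. GFRAL (ENSG00000187871, chromosome 6, 55327469 to 55402493) had 0 reads over the 6 parental libraries and 2, 5 and 2 reads over those of the parental DTP, chemoresistant and chemoresistant DTP groups. It was not tested, and any difference between groups was not detectable at this depth. GCLC (ENSG00000001084, chromosome 6, 53497341 to 53616970), the catalytic subunit of the rate-limiting enzyme of glutathione synthesis, was at 6.06 ± 0.356 FPKM in parental and 10.8 ± 1.33 in parental DTP cells. Its level was 41.2 ± 3.04 FPKM in the chemoresistant and 70.6 ± 3.75 in the chemoresistant DTP group. GCLM (ENSG00000023909), the modifier subunit of the same enzyme, was at 9.13 ± 1.51 and 15.4 ± 1.95 FPKM in parental and parental DTP cells and at 10.4 ± 1.52 and 22.6 ± 2.61 in chemoresistant and chemoresistant DTP cells. NFE2L2 (ENSG00000116044), which encodes NRF2, was at 15.8 ± 1.78, 34.4 ± 3.44, 37.3 ± 4.20 and 44.1 ± 2.49 FPKM in the same order.

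**Figure D1:**
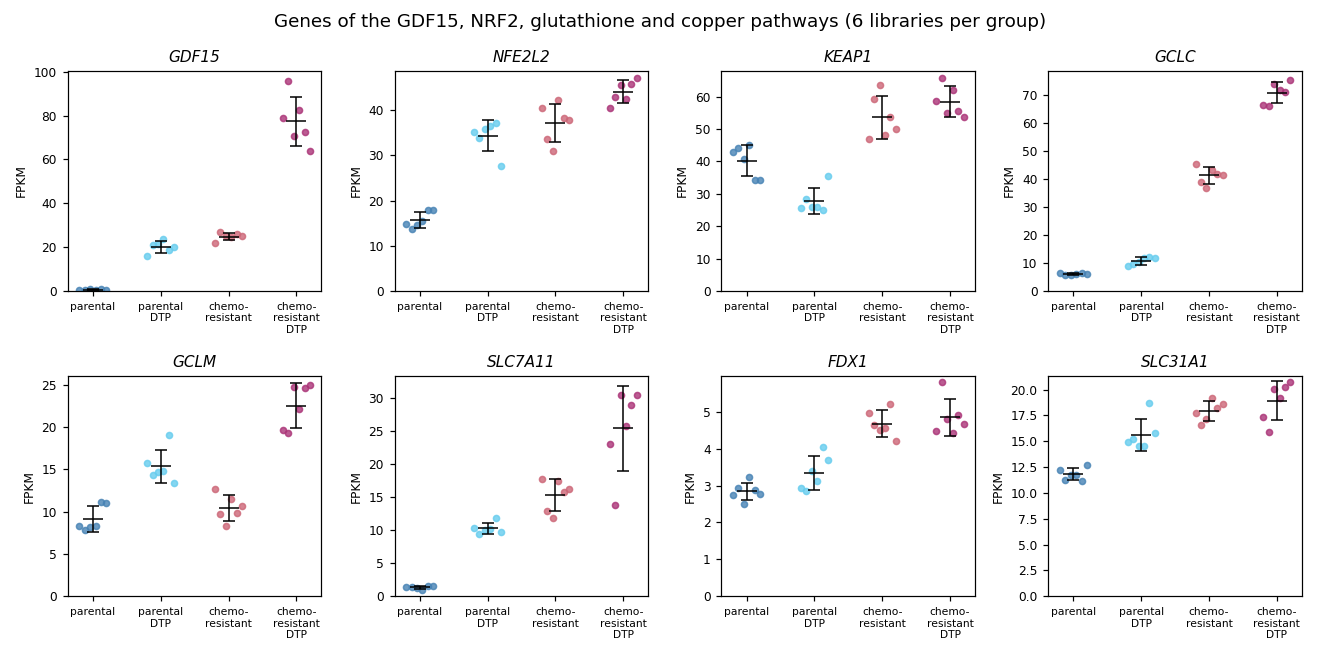
FPKM of 8 genes in each of the 24 libraries, by group; each point is a library and the bars give the mean and SD of 6. GDF15 ran from a mean of 0.607 FPKM in parental to 77.3 in chemoresistant DTP cells, and GCLC from 6.06 to 70.6.

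The comparison of parental DTP with parental cells asked how the persister state of the parental line differs from the line itself. In the persister cells of the parental line, genes of the integrated stress response and inflammatory chemokines rose together. Cytosolic heat shock proteins and genes of mitosis and DNA replication fell. The heat shock, mitosis and replication lists were also lower in chemoresistant than in parental cells (medians -1.30, -0.79 and -0.74). From chemoresistant to chemoresistant DTP cells their medians were 0.30, 0.12 and 0.07. Genes of the integrated stress response and NF-kB cytokines and chemokines were also higher in chemoresistant than in parental cells (medians 1.42 and 1.15). Their medians from chemoresistant to chemoresistant DTP cells were 0.17 and 0.06. For these falls and rises a trait of the parental libraries cannot be told apart from the persister state. The largest rises were in GDF15 (log2 fold change 3.71, SE 0.09, adjusted p = 9.49e-21), in CHAC1, a glutathione-degrading enzyme induced by stress (1.04 ± 0.222 to 24.995 ± 2.62 FPKM), and in CTH, which makes cysteine from cystathionine (1.85 ± 0.292 to 32.7 ± 2.79). ADM2, a secreted peptide hormone, and CXCL8, the chemokine interleukin-8, followed with log2 fold changes of 3.50 (SE 0.05) and 3.29 (SE 0.11). The deepest falls were in HSPA1A, the stress-inducible HSP70 (366 ± 47.6 to 33.6 ± 6.07 FPKM, log2 fold change -3.42), in HSPA8, the constitutive HSC70 (781 ± 40.9 to 84.4 ± 7.64 FPKM, -3.20), in HSPA1B (-2.50), in the co-chaperone DNAJA1 (-2.19) and in ACTB, cytoplasmic actin (1536 ± 228 to 466 ± 60.7 FPKM, -1.71). By the rule that picked these genes, all 6 libraries of one group lay beyond all 6 of the other.

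Among the genes fixed as targets of ATF4, the transcription factor of the integrated stress response, 34 of 36 rose and 1 fell (median log2 fold change 1.46, camera adjusted p = 1.31e-17). Besides GDF15, CHAC1 and CTH, TRIB3, a pseudokinase that feeds back on the response, rose from 7.85 ± 0.352 to 76.1 ± 4.17 FPKM. NF-kB cytokines and chemokines rose in 20 of 23 members and fell in 1 (adjusted p = 3.8e-08). They included PTGS2, the inducible cyclooxygenase (0.790 ± 0.0975 to 11.1 ± 0.612 FPKM), the neutrophil chemokine CXCL1 (15.4 ± 1.02 to 91.6 ± 6.67) and CCL20 (log2 fold change 2.31). Heat shock genes fell in 16 of 19 members with 0 rises (median -0.80, adjusted p = 1.4e-13). Mitosis genes fell in 25 of 29 with 0 rises (adjusted p = 4.78e-14), among them the kinesin KIF20A (49.9 ± 1.502 to 18.3 ± 1.44 FPKM), the mitotic kinases PLK1 (log2 fold change -1.15) and AURKB (-1.08), and cyclin A2, CCNA2 (-1.05). Of the DNA replication genes, 30 of 34 fell and 1 rose (adjusted p = 1.41e-17). UHRF1, which maintains DNA methylation at replication forks, fell from 39.4 ± 3.46 to 14.2 ± 1.44 FPKM, and the helicase subunits MCM4, MCM5 and MCM3 fell with log2 fold changes of -1.24, -1.18 and -1.10. Cholesterol and fatty acid synthesis genes fell in 18 of 32 and rose in 5 (adjusted p = 2.47e-06), with falls in INSIG1, a sensor of sterols (-1.21), in FASN, fatty acid synthase (-1.03), and in SQLE (-0.98) and HMGCS1 (-0.95), enzymes of cholesterol synthesis. Adjusted over the list alone, the counts of these 6 lists were the same except for NF-kB genes, with 21 rises and 1 fall. The 6 list calls held with an estimated correlation (adjusted p = 0.0008, 0.00366, 0.000235, 0.0427, 0.00347 and 0.0345 in the order given). Control lists moved in the same comparison: nuclear-retained RNAs, a measure of RNA quality, rose in 5 of 5 (median 0.71, adjusted p = 0.0294, and adjusted p = 0.438 with an estimated correlation), and histone transcripts, which lack a poly(A) tail, rose in 13 of 21 with 0 falls (adjusted p = 0.0771).

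Genes of glutathione synthesis and use rose in 19 of 28 and fell in 3, or 16 and 6 under relative log expression scaling. The list did not pass (adjusted p = 0.0676, and adjusted p = 0.41 with an estimated correlation). GCLC rose by a log2 fold change of 0.73 (SE 0.06) and GCLM by 0.70 (SE 0.10), as did SLC7A11, the cystine importer (1.35 ± 0.207 to 10.2 ± 0.834 FPKM), the detoxifying hydrolase HAGH (0.79) and the glutathione conjugate exporter ABCC1 (0.73). NRF2 targets rose in 21 of 38 and fell in 7 without passing as a list (median 0.37, adjusted p = 0.301). Without parental DTP libraries 5 and 6, 17 rose and 9 fell (median 0.14). Under relative log expression scaling 18 rose and 10 fell (median 0.195). Among the rises were HMOX1, haem oxygenase (1.33), CYP4F11 (1.03) and PIR (0.86). Levels of NRF2 targets in parental DTP libraries 5 and 6 stood apart: AKR1C3 was at 7.56 and 6.07 FPKM there and at 0.641 to 0.763 in libraries 1 to 4. NFE2L2 itself rose (1.08, SE 0.08) and KEAP1, the adaptor that targets NRF2 for degradation, fell (-0.52, SE 0.09). Cuproptosis genes rose in 5 of 15 and fell in 3, or 3 and 4 under relative log expression scaling (adjusted p = 0.955), the rises including the copper importer SLC31A1 (0.37), LIAS and LIPT1 of the lipoic acid pathway (0.50 and 0.39) and DLD, the subunit shared by the lipoylated dehydrogenase complexes (0.29). FDX1, a mitochondrial ferredoxin needed for protein lipoylation, had a log2 fold change of 0.17 (adjusted p = 0.0257), which no longer passed without parental library 3 (0.15), parental DTP library 5 (0.13) or parental DTP library 6 (0.15).

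Across all tested genes, 8994 changed in this comparison, of which 6283 rose and 2711 fell, and 470 changed at least 2-fold, 379 of them upward. The median log2 fold change of all genes was 0.14. Scaling by relative log expression factors took this shift out (median 0.00) and gave 4477 rises and 4413 falls, and 251 rises and 183 falls at 2-fold. After that scaling the list medians were 1.29 for ATF4 targets, 0.86 for NF-kB genes, -0.98 for heat shock, -0.76 for mitosis, -0.67 for replication and -0.51 for lipid synthesis genes, and the changes of FDX1 (0.03) and DLD (0.11) no longer passed.

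The comparison of chemoresistant DTP with chemoresistant cells asked the same of the resistant line. Here interferon-stimulated genes fell together and NRF2 targets rose, though with an estimated correlation the NRF2 list no longer passed (adjusted p = 0.0677). Interferon-stimulated genes were also higher in chemoresistant than in parental cells (median 3.38). For their fall a trait of the chemoresistant libraries cannot be told apart from the persister state. IFI6, an interferon-induced mitochondrial protein, fell from 264 ± 13.7 to 22.7 ± 4.83 FPKM (log2 fold change -3.50, SE 0.27, adjusted p = 1.4e-10), and ISG15, an interferon-induced ubiquitin-like modifier, from 559 ± 54.6 to 54.3 ± 15.0. The antiviral genes TRIM22 (13.97 ± 1.61 to 0.574 ± 0.153 FPKM), IFIT3 (45.4 ± 4.61 to 5.39 ± 0.536) and MX2 (10.7 ± 0.920 to 0.649 ± 0.213) completed the deepest falls. The largest rises were in ERRFI1, a feedback inhibitor of EGFR (15.96 ± 1.66 to 69.4 ± 6.33 FPKM), in AREG, the EGFR ligand amphiregulin (11.2 ± 0.241 to 49.7 ± 5.84), in GPAT3, an enzyme of triglyceride synthesis (log2 fold change 1.76), in the cornified envelope gene SPRR2D (27.5 ± 2.58 to 97.5 ± 27.1 FPKM) and in CXCL8 (1.74). GDF15 rose by 1.59 (SE 0.09). Except for GDF15, these genes were picked by a rule that asked for no overlap of the libraries. Those of GDF15 did not overlap either.

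Of the interferon-stimulated genes, 32 of 32 fell (median log2 fold change -2.14, adjusted p = 2.94e-36, and adjusted p = 0.0111 with an estimated correlation). NRF2 targets rose in 27 of 38 and fell in 4 (adjusted p = 3e-09, and adjusted p = 0.0677 with an estimated correlation). They included thioredoxin reductase, TXNRD1 (59.6 ± 3.095 to 134 ± 9.48 FPKM), NR0B1 (log2 fold change 1.30), HMOX1 (0.89) and GCLM (1.04, SE 0.10). Glutathione genes rose in 11 of 28 and fell in 7, or 8 adjusted over the list alone (adjusted p = 0.121). Among the 11 were GCLC (0.76, SE 0.06), glutathione reductase, GSR (20.8 ± 0.765 to 33.6 ± 1.57 FPKM), and SLC7A11 (0.66). NFE2L2 rose by 0.24 (SE 0.08, adjusted p = 0.0125), while KEAP1 had a log2 fold change of 0.13 (adjusted p = 0.25). ATF4 targets rose in 21 of 36 and fell in 1 (median 0.17, adjusted p = 1.15e-07, and adjusted p = 0.0171 with an estimated correlation). FGF21, a stress-induced hormone, rose from 0.937 ± 0.176 to 5.31 ± 1.37 FPKM, and CTH and PPP1R15A, which restores translation after stress, rose by 1.03 and 1.02.

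Metallothioneins, which bind zinc and copper, and genes of the zinc response rose in 4 of 5 with 0 falls (adjusted p = 0.00124, and adjusted p = 0.0121 with an estimated correlation). MT1F rose from 6.24 ± 0.610 to 17.8 ± 3.88 FPKM, MT2A from 293 ± 21.6 to 593 ± 137, and MT1X (log2 fold change 1.15) and the zinc exporter SLC30A1 (0.31) rose too. Chaperones of the endoplasmic reticulum rose in 12 of 20 with 0 falls, or in 13 adjusted over the list alone (adjusted p = 7.31e-05, and adjusted p = 0.077 with an estimated correlation). HSPA5, the main chaperone of that compartment, rose from 115 ± 2.35 to 226 ± 12.3 FPKM, and HYOU1 (0.62), the transcription factor XBP1 (0.55) and SEL1L (0.36) rose with it. Heat shock genes rose in 13 of 19 with 0 falls, or in 14 with 1 fall adjusted over the list alone (adjusted p = 2.38e-05, and adjusted p = 0.0111 with an estimated correlation), for example HSP90AA1 (108 ± 12.4 to 168 ± 22.4 FPKM) and its co-chaperones CHORDC1 (0.83) and STIP1 (0.61). Squamous differentiation genes rose in 12 of 26 and fell in 3 (adjusted p = 0.00534, and adjusted p = 0.252 with an estimated correlation), led by SPRR2D, SPRR3 (1.03), SCEL (0.76) and SPRR2E (0.73) of the cornified envelope. Cholesterol and fatty acid synthesis genes fell in 19 of 32 with 0 rises (adjusted p = 0.00033, and adjusted p = 0.102 with an estimated correlation). Stearoyl-CoA desaturase, SCD, fell from 136 ± 4.45 to 65.2 ± 11.6 FPKM, and SREBF1 (-0.96) and SREBF2 (-0.69), the transcription factors of lipid synthesis, fell with INSIG1 (-0.67). Cuproptosis genes rose in 4 of 15 and fell in 1 (adjusted p = 0.206), with rises in PDHA1 of pyruvate dehydrogenase (0.38) and DLD (0.30) among them and a fall in the copper exporter ATP7B (-0.26). FDX1 and SLC31A1 had log2 fold changes of 0.04 (adjusted p = 0.637) and 0.07 (adjusted p = 0.36). In all, 6586 genes changed (2820 rose, 3766 fell), 190 of them at least 2-fold (49 rose, 141 fell), and the median log2 fold change of all genes was -0.02.

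**Figure D2:**
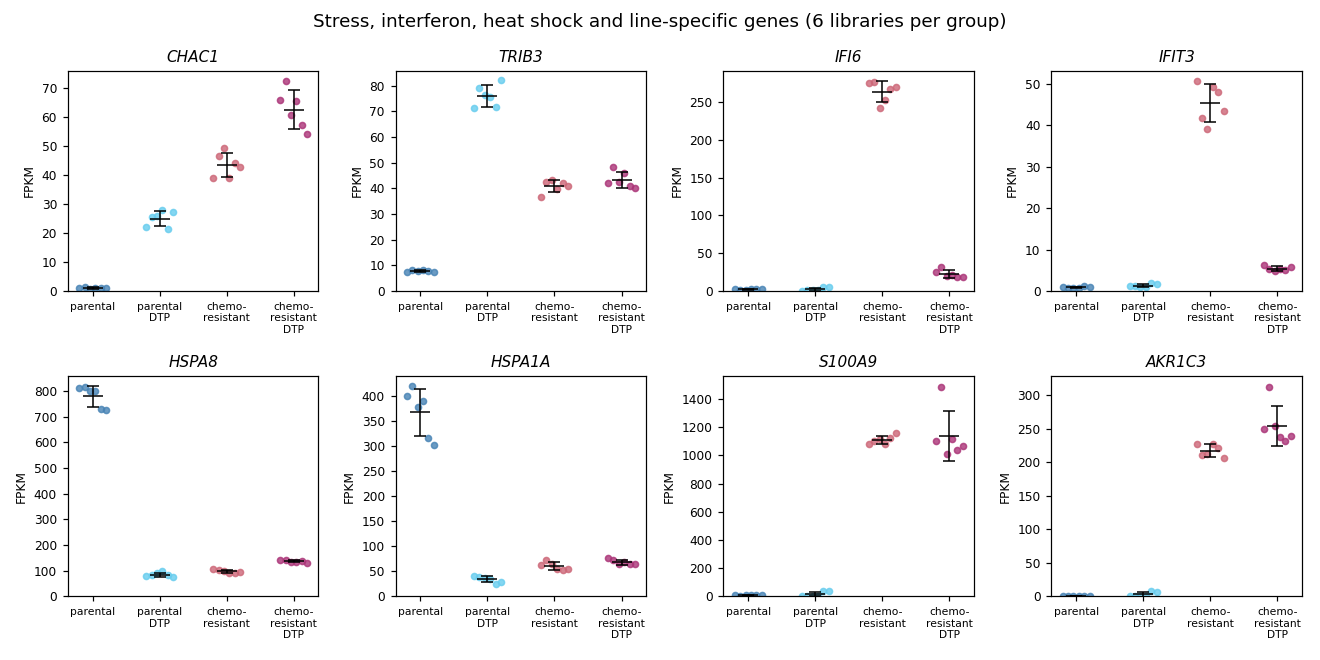
FPKM of 8 genes in each of the 24 libraries, by group; each point is a library and the bars give the mean and SD of 6. HSPA8 and HSPA1A were highest in the parental libraries (means of 781 and 366 FPKM), and IFI6 and IFIT3 in the chemoresistant ones (264 and 45.4 FPKM).

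The comparison of the chemoresistant with the parental line asked how the resistant cells differ outside the persister state. Chemoresistant cells had higher levels of interferon-stimulated genes, NRF2 targets and squamous differentiation genes and lower levels of heat shock, mitosis and DNA replication genes. With an estimated correlation the interferon, NRF2, squamous and mitosis lists no longer passed (adjusted p = 0.0987, 0.0807, 0.12 and 0.0677). S100A9, a calcium-binding protein of stressed epithelium, was at 6.62 ± 1.47 FPKM in parental and 1111 ± 29.8 in chemoresistant cells (log2 fold change 7.21, SE 0.39, adjusted p = 2.11e-14). The interferon-induced genes IFI27 (0.269 ± 0.0733 against 178 ± 19.1 FPKM) and BST2 (2.17 ± 0.480 against 433 ± 26.1) and the reductase AKR1C3 (0.610 ± 0.134 against 217 ± 9.28) were higher by log2 fold changes of 7.13, 7.11 and 7.09, and IFI6 by 6.34. Lower in chemoresistant cells were FKBP10, a collagen-folding isomerase (26.9 ± 0.896 against 1.38 ± 0.349 FPKM), the muscle-type tropomyosin TPM2 (47.7 ± 1.65 against 4.32 ± 3.07), the homeobox gene IRX1 (9.19 ± 0.758 against 0.188 ± 0.0428), the receptor TNFRSF8 (15.7 ± 1.47 against 1.02 ± 0.162) and HSPA8 (log2 fold change -3.00). As the rule that picked these genes asked, levels of the 2 groups did not overlap for any of them.

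Interferon-stimulated genes were higher in 32 of 32 (median log2 fold change 3.38, adjusted p = 2.29e-16, and adjusted p = 0.0987 with an estimated correlation). ISG15 was higher by 5.27. NRF2 targets were higher in 36 of 38 and lower in 1 (median 1.12, adjusted p = 2.01e-08, and adjusted p = 0.0807 with an estimated correlation), with AKR1B10 at 0.113 ± 0.0532 against 60.2 ± 1.68 FPKM and the near-identical AKR1C2 and AKR1C1 higher by 5.23 and 5.14. Glutathione genes were higher in 21 of 28, or 22 adjusted over the list alone, and lower in 3 (adjusted p = 0.00747, and adjusted p = 0.209 with an estimated correlation). They included CHAC1 (log2 fold change 4.45), GPX2, a glutathione peroxidase of epithelia (39.7 ± 2.09 against 287 ± 19.6 FPKM), SLC7A11 (2.79) and GCLC (2.58, SE 0.06, adjusted p = 3.61e-21). GCLM had a log2 fold change of 0.18 (adjusted p = 0.106), which passed only without parental library 5 (0.23), parental library 6 (0.23) or chemoresistant library 3 (0.24). NFE2L2 was higher by 1.19 (SE 0.08) and KEAP1 by 0.41 (SE 0.09). Squamous differentiation genes were higher in 22 of 26 and lower in 3 (adjusted p = 0.000285, and adjusted p = 0.12 with an estimated correlation), led by S100A9, S100A8 (5.65), S100A7 (4.98) and the protease KLK10 (3.52).

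ATF4 targets were higher in 32 of 36 and lower in 2 (adjusted p = 1.09e-09, and adjusted p = 0.00742 with an estimated correlation), with CHAC1, GDF15 (4.01, SE 0.09), CTH (3.18) and the stress sensor SESN2 (3.66 ± 0.164 against 32.5 ± 1.07 FPKM) changed most. NF-kB genes were higher in 20 of 23, or 21 adjusted over the list alone, and lower in 2 (adjusted p = 2.61e-06, and adjusted p = 0.00742 with an estimated correlation), for example the chemokine CCL5 (2.33 ± 0.273 against 44.2 ± 4.22 FPKM), TNFAIP2 (log2 fold change 3.52), CCL20 (2.82) and the cytokine IL1A (2.39). Heat shock genes were lower in 15 of 19 and higher in 2 (adjusted p = 5.07e-08, and adjusted p = 0.00347 with an estimated correlation), among them CHORDC1 (-2.83), HSPA1A (-2.60) and HSP90AA1 (-2.58). Mitosis genes were lower in 29 of 29 (adjusted p = 6.91e-12, and adjusted p = 0.0677 with an estimated correlation), including the proliferation marker MKI67 (59.2 ± 7.85 against 22.3 ± 2.67 FPKM) and the mitotic regulators BIRC5 (-1.19), AURKB (-1.21) and KIF20A (-1.25). Of the DNA replication genes, 32 of 34 were lower and 1 was higher (adjusted p = 1.4e-13, and adjusted p = 0.00676 with an estimated correlation), with UHRF1 (-1.57), the initiation factors MCM10 (-1.54) and GINS1 (-1.37) and the flap endonuclease FEN1 (-1.45) lowest. Cuproptosis genes were higher in 8 of 15 and lower in 6, or 6 and 7 under relative log expression scaling (adjusted p = 0.872). FDX1 and SLC31A1 were each higher by 0.56 and so was ATP7B. Histone transcripts were higher in 17 of 21, or 18 adjusted over the list alone, with 0 lower (adjusted p = 0.00134, and adjusted p = 0.108 with an estimated correlation).

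Of all tested genes, 10645 differed between the lines (6614 higher and 4031 lower in chemoresistant cells), 1830 of them at least 2-fold (1362 higher, 468 lower), and the median log2 fold change was 0.14. Relative log expression factors brought the median to 0.00 and the split to 5369 higher and 5288 lower genes, or 1052 and 728 at 2-fold. The difference of KEAP1 no longer passed under them (0.23), 0 heat shock genes were then higher and 15 lower, and the medians of the interferon, NRF2, ATF4, heat shock and mitosis lists became 3.29, 0.95, 1.26, -1.48 and -0.96.

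The comparison of the 2 lines within the DTP state asked whether their differences persist there. S100A9 (log2 fold change 6.79, SE 0.39), AKR1C3 (6.48, SE 0.31), AKR1B10 (5.95), BST2 (5.64) and S100A8 (5.54) were highest in chemoresistant relative to parental DTP cells. FKBP10 (31.1 ± 1.85 against 0.874 ± 0.336 FPKM), IRX1 (log2 fold change -3.10), the phospholipid transfer protein PLTP (8.80 ± 0.691 against 0.256 ± 0.0643 FPKM), TPM2 (-2.91) and CCDC8 (-2.87) were lowest. NRF2 targets were higher in 37 of 38 with 0 lower (median 1.21, adjusted p = 6.81e-22, and adjusted p = 0.00446 with an estimated correlation), with AKR1C1 and AKR1C2 higher by 4.83 and 4.78. Glutathione genes were higher in 18 of 28 with 0 lower (adjusted p = 3.06e-05, and adjusted p = 0.0436 with an estimated correlation): GCLC by 2.61 (SE 0.06), GPX2 by 2.11, CHAC1 by 1.29 and the transferase GSTM3 by 1.21. GDF15 was higher by 1.89, NFE2L2 by 0.35, KEAP1 by 1.05, GCLM by 0.53, FDX1 by 0.43 and SLC31A1 by 0.26, each past the threshold. Metallothioneins and zinc response genes were higher in 5 of 5 (adjusted p = 0.0025, and adjusted p = 0.0178 with an estimated correlation), MT1F by 1.61 and MT1X by 1.37. Squamous differentiation genes were higher in 21 of 26, or 22 adjusted over the list alone, and lower in 1 (adjusted p = 3.33e-13, and adjusted p = 0.00446 with an estimated correlation), with SPRR2D higher by 4.92 and S100A7 by 4.54. Interferon-stimulated genes were higher in 31 of 32 and lower in 1 (median 0.93, adjusted p = 3.19e-14, and adjusted p = 0.12 with an estimated correlation), with IFI27 higher by 4.19, IFI6 by 3.11 and ISG15 by 2.25. Cuproptosis genes were higher in 7 of 15 and lower in 2 (adjusted p = 0.388), the lower ones including LIPT2, a transferase of the lipoic acid pathway (-0.66). Histone transcripts were higher in 16 of 21, or 17 adjusted over the list alone, with 0 lower (adjusted p = 0.000352, and adjusted p = 0.077 with an estimated correlation). Parental DTP libraries 5 and 6 held S100A9 at 35.9 and 34.1 FPKM and IFI6 at 5.37 and 4.86, against 3.90 to 4.64 and 0.633 to 0.984 in libraries 1 to 4. In this comparison 8492 genes differed (4051 higher, 4441 lower), 721 of them at least 2-fold (415 higher, 306 lower), with a median log2 fold change of -0.02.

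**Figure D3:**
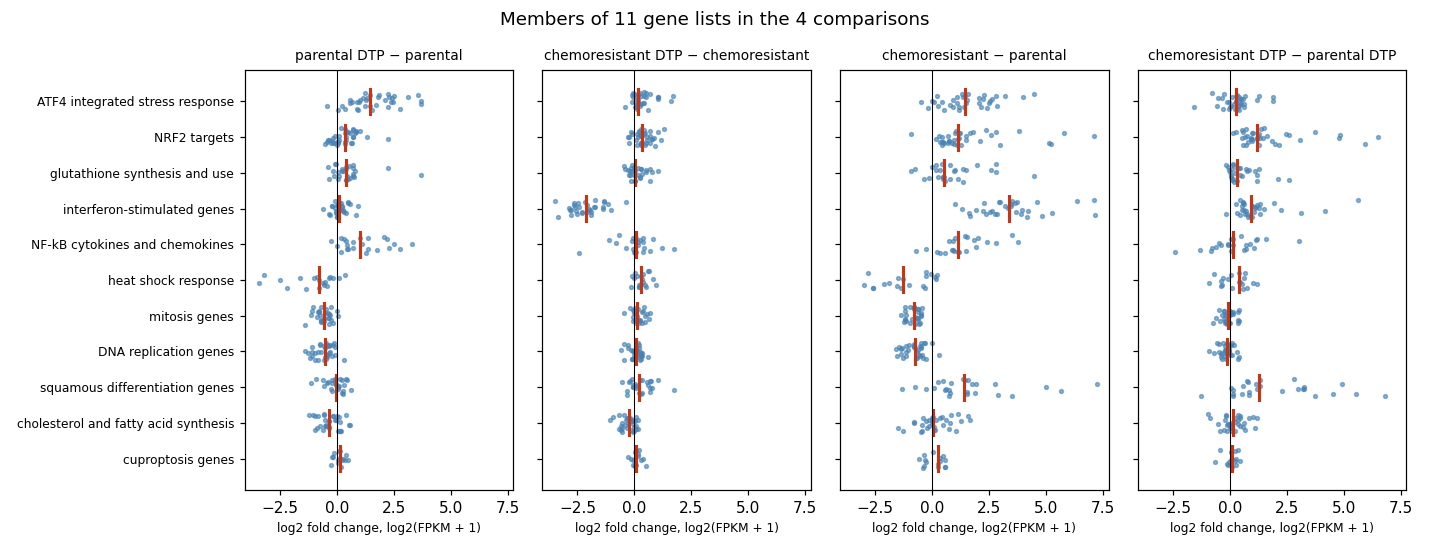
Log2 fold changes of the measured members of 11 gene lists in 4 comparisons; each point is a gene, the red bar is the list's median and the axis is on the log2(FPKM + 1) scale. Interferon-stimulated genes had a median of 3.38 between the lines and of -2.14 from chemoresistant to chemoresistant DTP cells.

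Whether the 2 lines changed alike on entering the DTP state was tested as the difference of the DTP changes, chemoresistant minus parental. Most of the stress response and heat shock genes that changed in the parental line changed less or the other way in the chemoresistant line. The parental and chemoresistant libraries enter this difference, so a trait common to either group cannot be told apart from a differing DTP change. Interferon-stimulated genes fell in the chemoresistant line (32 of 32), while in the parental line 11 rose and 1 fell, or 6 and 7 under relative log expression scaling and 7 and 5 without parental DTP libraries 5 and 6. Several of these genes stood higher in those libraries, such as BST2 (9.53 and 10.1 FPKM against 0.709 to 1.25 in libraries 1 to 4, and a parental mean of 2.17). The list call for the difference was lost with an estimated correlation (adjusted p = 0.0976). The difference was 3.69 (SE 0.08, log2) for HSPA8, 3.61 for HSPA1A, 2.70 for HSPA1B, 2.51 for DNAJA1 and 2.40 for FGFBP1, a carrier of fibroblast growth factors. It was -3.60 (SE 0.07) for OASL, -3.35 for IFIT2, -3.24 for ADM2, -3.23 for TRIM22 and -3.22 for IFI6. The DTP change of GDF15 was smaller in the chemoresistant line by a difference of -2.12 (SE 0.12, adjusted p = 3.84e-13), that of NFE2L2 by -0.83 and that of SLC31A1 by -0.30, and that of KEAP1 was greater by 0.65. For GCLC the difference was 0.03 (SE 0.09, adjusted p = 0.76), and for FDX1 -0.13 (adjusted p = 0.227). GCLM had a difference of 0.35 (SE 0.14, adjusted p = 0.0358). Leaving out any of 12 libraries ended that call, with values between 0.29 and 0.34: parental 5 or 6, chemoresistant 2, 3 or 5, parental DTP 2, 3, 4 or 6, or chemoresistant DTP 3, 5 or 6.

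ATF4 targets had a lower DTP change in the chemoresistant line in 32 of 36 and a higher one in 2 (median difference -1.23, adjusted p = 1.91e-11, and adjusted p = 0.00446 with an estimated correlation). CHAC1 (-3.16), TRIB3 (-3.04), CTH (-2.54) and DDIT3, the transcription factor CHOP (-2.42), differed most. NF-kB genes were lower in 19 of 23 and higher in 3 (adjusted p = 1.37e-05, and adjusted p = 0.0111 with an estimated correlation), with CCL5 (-2.58), CXCL1 (-2.45), TNFAIP2 (-2.38) and PTGS2 (-2.36) in front. Interferon-stimulated genes were lower in 32 of 32 (adjusted p = 1.48e-16, and adjusted p = 0.0976 with an estimated correlation). Without parental DTP libraries 5 and 6, a test chosen after the values were seen, 32 were still lower (median difference -2.28 against -2.36 with them, adjusted p = 4.55e-17). Heat shock genes were higher in 17 of 19, or 18 adjusted over the list alone, with 0 lower (adjusted p = 1.4e-13, and adjusted p = 0.000235 with an estimated correlation). Mitosis genes were higher in 26 of 29, or 27 adjusted over the list alone, with 0 lower (adjusted p = 2.39e-13, and adjusted p = 0.0492 with an estimated correlation), for example CCNA2 (1.54) and the checkpoint kinase TTK (1.14), and replication genes in 28 of 34, or 29 adjusted over the list alone, with 2 lower (adjusted p = 2.23e-13, and adjusted p = 0.00676 with an estimated correlation), for example UHRF1 (1.69), MCM4 (1.37) and CLSPN (1.36). Of the control lists, nuclear-retained RNAs were lower in 4 of 5 with 0 higher (median -0.79, adjusted p = 0.109) and histone transcripts in 13 of 21 with 0 higher (adjusted p = 0.137). Glutathione genes were lower in 16 of 28 and higher in 4 (adjusted p = 0.457), with GSR at 1.05 and the transferase GSTM4 at -0.87. The DTP change differed for 8764 genes (2812 higher, 5952 lower) and at least 2-fold for 1241 (292 higher, 949 lower), with a median difference of -0.17. Under relative log expression factors the median was -0.01 and the splits were 4252 and 4565, and 522 and 642. The medians of the ATF4, NF-kB, heat shock and mitosis lists were then -1.03, -0.88, 1.37 and 0.96, SLC31A1 no longer passed (-0.11), and GCLC passed with a difference of 0.22.

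Across the 13729 genes, the DTP changes of the 2 lines had a Pearson r of -0.15 and a Spearman rho of -0.22; genes are not independent replicates, so no p-value is given. Both lines shared 916 rises and 529 falls, where independent lists of the same lengths would share 1291 and 744. In 2298 genes a rise in the parental line met a fall in the chemoresistant line (1723 for independent lists), and in 963 the reverse (557). The parental DTP change and the difference between the lines ran together: 4703 genes were higher in both and 2038 lower in both (3027 and 796 for independent lists), such as GDF15, CHAC1, CTH and, among the falls, HSPA8 and HSPA1A. Both comparisons use the 6 parental libraries. Their fold changes had a Pearson r of 0.58 and a covariance of 0.19, against 0.53 and 0.01 for simulated unchanged groups measured against the same controls, a difference of 0.18 in covariance. With parental libraries 1 to 3 serving one comparison and 4 to 6 the other, 5811 genes shared their direction, and 5898 with these sets exchanged, against 6741 with all 6. The simulation and the split address the spread of single libraries only. A shift common to all 6 parental libraries would pass both, and the overlap was not recomputed under relative log expression scaling.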

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

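The chromosome window tests, the tests on parental DTP libraries 5 and 6, and those of scaling and of single libraries on the heat shock genes were chosen after the result was seen, as were the lists of which libraries to leave out together; the tests of GC content and length and the splits of the samples were planned before.

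In 180 groups of 6 libraries, 18 had 1 library far from the other 5 by Dixon's criterion, where chance alone gives about 1 in 20. Chemoresistant DTP library 2 accounts for 11 of them. Its summed FPKM was 346165 against 306431 to 316900 in the others, and it was highest in S100A9 (1490 FPKM), AKR1C3 (312.8), BST2 (233.2), S100A8 (124.2), AKR1B10 (103.5), AREG (60.97), ACTB (700.3), DNAJA1 (59.25) and FDX1 (5.804) and lowest in HSPA1B (28.96). Parental DTP library 6 was lowest in NFE2L2 (27.75 FPKM) and highest in KEAP1 (35.59), and parental DTP library 5 highest in DNAJA1 (48.69) and SLC31A1 (18.69). The others were parental library 2 for CHAC1 (1.462 FPKM), chemoresistant DTP library 1 for MX2 (1.066) and the summed FPKM of chemoresistant library 3 (323726).

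The DTP change differed between the lines, by the test of the difference itself, for 84 of the 92 genes named in the DTP comparisons. Some of these genes were named for the size of this difference, and of all 13729 tested genes 8764 (63.84%) differed. Camera called 8 lists for the difference. It sets a list against the other genes and not against no difference, and the median difference of all tested genes was -0.17. The list medians of the difference (chemoresistant minus parental, log2) were -1.23 for ATF4 targets, -1.001 for NF-kB genes, -2.36 for interferon-stimulated genes, 1.17 for heat shock genes, 0.76 for mitosis, 0.50 for replication, 0.13 for squamous differentiation genes and 0.0894 for NRF2 targets. Without parental DTP libraries 5 and 6 the last 2 became 0.35 and 0.18, and under relative log expression scaling 0.23 and 0.24. With an estimated correlation 3 of these calls were lost: those of the interferon (adjusted p = 0.0976), squamous (adjusted p = 0.215) and NRF2 lists (adjusted p = 0.556).

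Among stress and secreted factors FGF21 (0.99) and HYOU1 (0.54) had differences above 0, and these had differences below it: CHAC1 (-3.16), TRIB3 (-3.04), ADM2 (-3.24), CTH (-2.54), DDIT3 (-2.42), GDF15 (-2.12), SLC7A11 (-1.60), XBP1 (-1.18), PPP1R15A (-1.22), HSPA5 (-0.56) and SEL1L (-0.53). So did the chemokines and inflammatory genes CCL5 (-2.58), CXCL1 (-2.45), TNFAIP2 (-2.38), PTGS2 (-2.37), CCL20 (-1.96) and CXCL8 (-1.56), the interferon genes OASL (-3.60), IFIT2 (-3.35), TRIM22 (-3.23), IFI6 (-3.22), IFIT3 (-3.12), ISG15 (-3.02) and MX2 (-2.82), and the autophagy genes GABARAPL1 (-1.55), MAP1LC3B (-1.44), ULK1 (-0.92) and MITF (-0.69). Heat shock genes lay above 0, with HSPA8 (3.69), HSPA1A (3.61), HSPA1B (2.70), DNAJA1 (2.51), HSP90AA1 (2.25), CHORDC1 (2.16) and STIP1 (1.49), as did the cell cycle genes UHRF1 (1.69), CCNA2 (1.54), MCM4 (1.37), CLSPN (1.36), MCM3 (1.35), KIF20A (1.33), PLK1 (1.20), TTK (1.14), MCM5 (0.73) and AURKB (0.62). In epithelial genes the values were FGFBP1 (2.40), SPRR2D (2.02), KRT6A (1.71), KRT6C (1.55), KRT6B (1.31), SPRR3 (1.26), SPRR2E (0.92), SCEL (0.85), DSG3 (-1.30), AREG (-0.38) and ERRFI1 (0.47). For redox and metal genes they were NR0B1 (1.73), GSR (1.05), MT2A (0.59), TXNRD1 (0.44), GCLM (0.35), KEAP1 (0.65), GSTM4 (-0.87), NFE2L2 (-0.83), PIR (-1.08), HAGH (-0.75), ABCC1 (-0.73), CYP4F11 (-0.73), SLC31A1 (-0.30), ATP7B (-0.34), LIAS (-0.49) and LIPT1 (-0.43), and for metabolic and other genes ACTB (1.65), GPAT3 (1.49), SQLE (0.84), FASN (0.69), INSIG1 (0.55), HMGCS1 (0.43), PDHA1 (0.53), SREBF1 (-1.01), SREBF2 (-0.85) and SCD (-0.71).

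Each count of changed genes was set against 100 splits of the same libraries, and in each case 1 of the 100, the real one, gave as many. This argues against a chance division of these libraries, though not against differences between cultures, which the labels do not set apart. For the difference of DTP changes, states were shuffled within each line. That also removes the DTP changes themselves, so this count was not set against equal changes in the lines. For parental DTP against parental the counts were 8994 genes with a highest other split of 6727, and 470 against 141 at 2-fold. The chemoresistant DTP comparison gave 6586 against 4404 (190 against 70 at 2-fold), the lines 10645 against 8129 (1830 against 668), their DTP states 8492 against 6450 (721 against 308), and the difference of DTP changes 8764 against 1073 (1241 against 129).

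Genes typical of the chemoresistant line appeared at low level in parental DTP libraries 5 and 6, and a candidate explanation is RNA or reads from chemoresistant-line samples. Of 32 genes at 20 FPKM or more in chemoresistant cells and at 20 times the parental level or more, 84.4% (27) lay within 2-fold of the excess predicted from 1.45% of the chemoresistant plus 0.65% of the chemoresistant DTP level, with ratios of observed to predicted from -0.97 to 3.13. In the interferon and NRF2 lists, libraries 1 to 4 held 31 members at 1 FPKM or more and at over 0.2 of the chemoresistant level. Their median difference was 0.111 (log2, SE 0.052). This SE came from resampling the members and holds no spread between libraries. The value argued against an interferon or NRF2 response of these cultures for such members only. Genes far below the chemoresistant level in libraries 1 to 4, such as IFI6 and AKR1C3, were left out of this test. A response limited to genes of that kind therefore stays open. An exchange of whole libraries was argued against by a median level of 4.86% of the chemoresistant one in libraries 5 and 6, where libraries 1 to 4 stood at 2.33% to 2.63%. Where such RNA would have entered stays open, as does a further difference of these cultures: the same libraries held FN1 at 0.278 and 0.385 FPKM (3.81 to 8.98 in libraries 1 to 4), and COL1A2 and SPARC were lower too, which added RNA does not account for.

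Heat shock genes were highest in the parental libraries, which both comparisons against that group share. In 12 of 19 members the lowest parental library exceeded the highest of the other 18 libraries. GC content and gene length were argued against, since the list's median in parental DTP against parental was -0.80 before and -0.888 after their trend was removed. Under the other scalings the median closest to 0 was -0.863, and with a single library left out it was -0.766. Neither check could have brought it near 0. The relative log expression factors ran only from 0.882 to 1.082, and the 12 members named above were separated in every library. The checks show only that the list's fall rests neither on these scalings nor on a single library. How the parental cultures were handled before extraction may account for the high parental levels and stays open, as does a difference in cell state. The 2 were not tested apart.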

How the results depend on the processing

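The alternatives were planned before the data were examined, except those that leave out libraries 5 and 6 of the parental, parental DTP or chemoresistant DTP group or chemoresistant libraries 1 to 3 or 4 to 6, whose tests were chosen after the result was seen; none of these moved a count by over 1.5 times. No value of a named gene reversed. Under relative log expression scaling the balance of rises and falls turned in 19 of 150 pairs of list and comparison, 0 of them past the threshold with camera, such as the respiratory chain (9 rises and 2 falls to 2 and 7) and endoplasmic reticulum chaperones (9 and 4 to 9 and 10) in parental DTP against parental cells. Of 1785 values of 133 named genes under alternatives, 1773 kept their direction and side of the threshold, 10 no longer passed and 2 newly passed, where leaving out libraries counts once per value, by its strongest effect. Library by library, 17 omissions ended a call (of GCLM, FDX1 or GCSH) and 3 added one (GCLM). Counts of genes changed at least 2-fold depended on the scale, which damps genes at low levels. In the order parental DTP against parental, chemoresistant DTP against chemoresistant, chemoresistant against parental, chemoresistant DTP against parental DTP and the difference of DTP changes, they were 470, 190, 1830, 721 and 1241. They became 1690, 528, 3501, 1613 and 2898 with voom on recovered reads and 1485, 469, 3359, 1477 and 2719 with a pseudocount of 0.1. Without a filter, 16484 genes differed between the lines, more genes being tested, and among protein coding genes alone 789 differed at least 2-fold in their DTP change, fewer being tested. List calls went from 46 to 23 with an estimated correlation and to 120 with fry, which tests a list against no change and not against other genes, and stayed at 46 without parental DTP libraries 5 and 6. Of the lists that camera did not call, fry called 11 in the direction opposite to camera: for parental DTP against parental cuproptosis (adjusted p = 0.00455), ferroptosis (2.04e-08), hypoxia (3.98e-05) and tricarboxylic acid cycle genes (0.000287), for chemoresistant DTP against chemoresistant p53 targets (0.0327), between the lines cuproptosis (0.00365) and lipid synthesis genes (1.02e-05), and for the difference ferroptosis (1.54e-05), endoplasmic reticulum (0.00281), persister-associated (0.00141) and epithelial junction genes (8.51e-06). Leaving out each library in turn gave 8581 to 9552 and, at 2-fold, 452 to 500 genes for parental DTP against parental, 6186 to 7241 and 187 to 196 for chemoresistant DTP against chemoresistant, 10367 to 11037 and 1812 to 1846 between the lines, 8055 to 8736 and 700 to 778 between their DTP states, and 8531 to 9218 and 1181 to 1272 for the difference. The r of the DTP changes between the lines ran from -0.17 to -0.13. GCSH, lower in chemoresistant than parental DTP cells (-0.42), no longer passed without parental DTP library 5 (-0.31) or chemoresistant DTP library 1 (-0.35).

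The replicate numbers did not pair the libraries: over 36 same-number pairs the correlation of deviations from the group means ran from -0.385 to 0.403, with 12 over 0.1, and the own number correlated best in 8 of 72 cases. With the number as a block, the counts were 8965, 6629, 10674, 8552 and 8819 genes, and it moved no count by over 1.5 times. A count model with another tool's own size factors had been planned and was not run, since the values are FPKM. Depth limits what can be said of GFRAL, with at most 3 reads in a library.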

Other observations

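Biology outside the comparisons above included autophagy, cell death and epithelial identity. In parental DTP against parental cells MAP1LC3B, the autophagosome marker LC3B, rose from 8.46 ± 0.412 to 34.5 ± 2.27 FPKM, its relative GABARAPL1 from 5.51 ± 0.459 to 19.4 ± 1.33 and the initiating kinase ULK1 from 2.96 ± 0.233 to 7.88 ± 0.706 (SD, n = 6 each). The lysosome and autophagy list as a whole rose in 16 of 30 and fell in 5 there without passing (adjusted p = 0.269, and adjusted p = 0.511 with an estimated correlation). Between the lines it was higher in 23 of 30 and lower in 6 (adjusted p = 0.0345, and adjusted p = 0.12 with an estimated correlation), with GPNMB, a lysosomal glycoprotein, higher by a log2 fold change of 1.66 and WIPI1 lower (-1.59). Targets of p53 were higher in 17 of 24 and lower in 5 between the lines (adjusted p = 0.0562), among them the death effectors BBC3 (0.182 ± 0.0456 against 2.91 ± 0.295 FPKM) and PMAIP1 (2.16 ± 0.231 against 9.44 ± 0.760) and the cell cycle inhibitor CDKN1A (1.17 ± 0.225 against 4.84 ± 0.672). In parental DTP cells 17 p53 targets rose and 3 fell (adjusted p = 0.0771).

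Persister-associated genes were higher in 18 of 26 and lower in 8 between the lines (adjusted p = 0.316). ALDH1A1, a retinaldehyde dehydrogenase of tolerant cells, was at 0.907 ± 0.0987 against 13.1 ± 1.41 FPKM, IGFBP3 at 2.53 ± 0.493 against 26.0 ± 1.20 and FGFR3 at 5.06 ± 0.5001 against 18.5 ± 1.67, while the receptor kinase AXL was lower (6.54 ± 0.785 against 0.618 ± 0.120). Entry into the DTP state gave 15 rises and 7 falls of this list in the parental line (adjusted p = 0.924) and 8 of each in the chemoresistant line, or 9 of each adjusted over the list alone (adjusted p = 0.771). Basal squamous genes moved both ways: KRT14, a basal keratin, was at 258 ± 20.5 FPKM in parental and 44.1 ± 2.53 in chemoresistant cells, while KRT16 (3.14 ± 0.359 against 18.4 ± 1.74), KRT15 (95.3 ± 8.04 against 283 ± 11.2) and the desmosomal cadherin DSG3 (log2 fold change 1.74) were higher (14 of 25 higher, 8 lower, adjusted p = 0.627). In parental DTP cells 12 rose and 11 fell, or 5 and 13 under relative log expression scaling (adjusted p = 0.115), with KRT6A down from 1922 ± 123 to 782 ± 83.2 FPKM and DSG3 up by 1.46.

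The remaining lists gave the following values, in the order parental DTP against parental, chemoresistant DTP against chemoresistant, the lines, and their DTP states. Copper transport genes (18 measured) had 9, 5, 11 and 9 rises and 2, 8, 4 and 7 falls, ferroptosis genes (22) 8, 9, 13 and 12 rises and 5, 4, 4 and 4 falls, and drug transporters (11) 5, 3, 9 and 6 rises and 1, 3, 2 and 1 falls. Repair genes (31) had 10, 8, 7 and 7 rises and 11, 7, 18 and 13 falls, hypoxia and glycolysis genes (30) 13, 4, 16 and 13 and 10, 12, 6 and 9, and tricarboxylic acid cycle genes (30) 13, 10, 9 and 7 and 8, 4, 11 and 7. Mesenchymal genes (19) had 4, 4, 10 and 9 rises and 5, 2, 6 and 3 falls and mitochondrial mRNAs (13) 5, 1, 2 and 0 and 2, 1, 6 and 6. None of these 8 passed in these 4 comparisons. Epithelial junction genes (25) had 11, 8, 15 and 11 rises and 8, 5, 5 and 4 falls and passed between the DTP states (adjusted p = 0.046, and adjusted p = 0.288 with an estimated correlation). Respiratory chain genes (35) had 9, 6, 27 and 26 rises and 2, 0, 3 and 2 falls and passed there too (adjusted p = 0.00031, and adjusted p = 0.6 with an estimated correlation), as did ATF4 targets (23 higher, 8 lower, adjusted p = 0.00545, and adjusted p = 0.219 with an estimated correlation) and lysosome genes (18 higher, 8 lower, adjusted p = 0.032, and adjusted p = 0.117 with an estimated correlation). Adjusted over the list alone, the counts of these lists differed for copper transport (8 rises in the first comparison), repair (11 rises in the first), drug transporters (4 rises in the second), hypoxia and glycolysis (14 rises in the fourth), the tricarboxylic acid cycle (6 rises in the fourth), the respiratory chain (7 and 2 rises in the first and second) and lysosome genes (19 rises in the fourth). Under relative log expression scaling repair genes had 4 rises and 18 falls in the first comparison. Tricarboxylic acid cycle genes then had 7 rises and 12 falls there, and 6 and 20 between the lines. This scaling turned the medians of the ferroptosis, epithelial junction, hypoxia, tricarboxylic acid cycle, respiratory chain and mitochondrial lists below 0 in the first of these comparisons. Squamous differentiation genes had 5 rises and 8 falls in parental DTP cells (adjusted p = 0.0487, and adjusted p = 0.443 with an estimated correlation), or 5 and 11 without parental DTP libraries 5 and 6, and mitosis genes 12 rises and 2 falls in chemoresistant DTP cells (adjusted p = 0.00638, and adjusted p = 0.545 with an estimated correlation).

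Cell type markers and single libraries gave these values. Of the fibroblast, leukocyte, endothelial and glandular markers 5, 1, 1 and 2 were measured, and 0 erythroid ones, and between the lines 3, 0, 1 and 1 of them were higher and 0, 0, 0 and 1 lower. The fibroblast gene COL1A2 was at 1.90 to 2.70 FPKM in chemoresistant libraries 4 to 6 and at most 0.0311 in 1 to 3, at 1.503 to 2.235 in chemoresistant DTP libraries 1 to 3 and at most 0.019 in 4 to 6, and SPARC of the mesenchymal list followed it (2.632 to 3.597 against at most 0.211 in the chemoresistant group). The liver transcripts ALB, for albumin, AFP, APOA1, APOA2 and FGB were chosen after their values were seen. ALB was at 6.49, 4.59 and 3.81 FPKM in chemoresistant libraries 1 to 3, at 0.741, 0.678 and 0.818 in libraries 4 to 6, and at 14.03 and 5.77 in chemoresistant DTP libraries 5 and 6, with 0 in the parental group. AFP and APOA1 ran the other way within the chemoresistant group, at 0.888 to 1.38 and 0.0894 to 0.383 FPKM in libraries 1 to 3 and at 4.79 to 7.59 and 1.80 to 2.46 in libraries 4 to 6. APOA2 ran like ALB (3.16 to 5.82 against 0.449 to 0.710 FPKM) and FGB was alike in both sets (1.28 to 1.86). Chemoresistant DTP libraries 5 and 6 were high in AFP (19.6 and 7.75 FPKM), APOA1 (6.52 and 2.34), APOA2 (11.8 and 5.93) and FGB (8.44 and 3.26) as well. The origin of these liver and collagen transcripts was not tested.

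Blocks of neighbouring genes differed between the lines, by tests chosen after the result was seen except that of GC content and length. Over 201 windows of 10 Mb with at least 20 protein-coding genes, the median log2 fold change lay beyond 0.4 in both line comparisons in 9, of which 6 were lower and 3 higher in chemoresistant cells, and 0 did in any of 100 shuffles of gene positions. The strongest was on chromosome 11 from 110 to 120 Mb (-0.90 between the lines and -1.01 between their DTP states), and chromosome 11 from 50 to 60 Mb was higher (0.70 and 0.89). GC content and gene length were argued against, since all 9 stayed beyond 0.4 after their trends were removed. A difference in DNA copy number between the lines stays open. In the DTP comparisons, where the line does not change, the largest median of the 9 windows was 0.197 in size, but 196 of all 201 windows lay within 0.2 there, so this does not decide it, and no DNA was measured.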
